A study of Mus musculus with 12 samples.

How the data were processed

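RNA from mouse liver was sequenced on an Illumina Genome Analyzer IIx. Per the labels' protocols, males aged 10 weeks received a methionine- and choline-deficient (MCD) diet for 3 weeks, a diet that produces steatohepatitis in mice, and RNA from 2 animals was mixed in equal parts into each pool. The 12 libraries form 3 groups of 4 pools. The control group carried Lyzs-Cre, a Cre recombinase expressed from the lysozyme 2 locus in myeloid cells. The KO group carried Lyzs-Cre and lacked p38γ and p38δ, the stress-activated kinases encoded by Mapk12 and Mapk13. The anti-Ly6G group carried Lyzs-Cre and received an antibody against Ly6G, a surface protein of neutrophils. The titles of these samples read GR1, and their source names read Ly6G. The labels also speak of 12 males per genotype, which 4 pools of 2 do not account for. If the pools hold separate animals, p-values here measure the spread between pools of 2 animals. A further label gives the origin of the mitochondria, with the protocol describing conplastic mice, whose nuclear genome comes from one strain and whose mitochondrial DNA comes from another. This label was C57 in the control pools and in KO pools 1 and 2, and NZB in KO pools 3 and 4 and in all anti-Ly6G pools. All samples carried the strain label C57BL/6.

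The authors deposited a normalized signal per gene, and cutadapt 1.2.1, RSEM 1.2.3, Bowtie2 2.0.6, edgeR and the genome build GRCm38 are named per the submitters' processing notes, without their roles. The version of edgeR, the gene annotation and the rule by which genes entered the table are not given in the sources used here. The deposited signal of 11791 genes came in 12 columns, each summing to between 0.922 M and 1.06 M. In each column every value was a whole multiple, within 0.01, of the value of 1 read (100% of values). These multiples were taken as reads. TMM factors recomputed from them gave the deposited scaling back with a ratio of 1 in all 12 columns, so the signal is reads scaled to a TMM-adjusted library size (RPM). A stricter test of the low values passed in 4 columns, and the other 8 hold too few low values for it. Recovered totals were 14.4 to 19.9 M reads in control, 18.8 to 22.3 M in KO and 13.1 to 21.0 M in anti-Ly6G pools. A count of 3 reads corresponds to a signal of 0.125 to 0.242, depending on the library. Intervals and floors of this kind cover counting error only.

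Gene symbols, biotypes and GRCm38 coordinates came from GENCODE vM21, in which 11672 of the 11791 IDs were found. The uniqueness of a gene's sequence was measured as the percent of its annotated 25-mers that occur in no other annotated gene. Of 11665 genes with such a value, 73.1% had at least 90% unique 25-mers. The protocol does not state how reads shared between near-identical genes were assigned or whether strand was used, so genes with few unique 25-mers are reported as uncertain.

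The tests were limma-trend fits (limma 3.58.1 in R 4.3.3) on log2(signal + 0.5), with group as the only term, all 12 libraries in 1 fit and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(signal + 0.5) scale, which understates the change of low genes. The design chosen before the data were examined named edgeR's quasi-likelihood test for counts and limma-trend for normalized values. Since the table holds a normalized signal, limma-trend gave the reported values, and edgeR 4.0.16 on the recovered reads was an alternative. A filter asked for a mean of at least 1 in at least 1 group and removed 0 genes. All genes also reached 1 in at least 4 libraries, so the planned fits without a filter and with a minimum in 4 libraries were identical to the reported one and were not run apart. The 3 comparisons were KO against control, anti-Ly6G against control and KO against anti-Ly6G. The edgeR test called 76 genes higher and 77 lower, 1786 and 1772, and 1589 and 1580 in these comparisons.

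Before the data were examined, 35 lists of genes were fixed for liver cell types and pathways. Of these, 32 had at least 5 measured members and were tested with camera (limma, preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists). Camera was run on the same log2(signal + 0.5) values and not on log2 CPM as first planned. Members past the threshold were counted over all genes tested and, separately, adjusted over the list alone.

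Named genes followed a rule fixed before the data were examined. For each comparison with control it took the targeted genes, the 8 largest changes in each direction, and the 3 members of lowest p in each list that passed camera or held a called gene. The 5 most abundant neutrophil genes were always taken, and KO against anti-Ly6G took the targeted genes and the 5 largest changes in each direction. Genes past the threshold in the same direction in both comparisons with control gave the 5 with the largest change in the weaker of them. The largest changes needed an adjusted p under 0.05, a mean of at least 1 in either group and no overlap between the 4 and 4 pools, and left out unnamed gene models. Where the design said edgeR adjusted p, the limma value was used. Ciart, listed under a model name in the table, was kept because its current symbol is a proper name. For anti-Ly6G against control, of lists that did not pass camera the text may name the member of lowest p alone. Genes named outside the rule are said to have been chosen after their values were seen. Mapk13 and Ly6g are not analysed here.

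Alternatives were other pseudocounts (5 and 0.05), a mean of at least 5, DESeq2 and upper-quartile scaling factors, DESeq2 1.42.0, limma-voom with and without sample weights, fits of only the groups compared, the replicate number as a block, the mitochondria label as a covariate or matched, stricter thresholds, and each library left out in turn. Effects against the shared controls were set beside 20 simulated experiments of unchanged groups. The fits were tested on simulated reads for the 11791 genes, with 200 genes changed per comparison with control. For 1.5-fold, 2-fold and 4-fold changes, recovery was 59.7%, 88.1% and 98.5% in KO against control. It was 65.7%, 97.0% and 100% in anti-Ly6G against control, and 68.4%, 94.0% and 99.2% in KO against anti-Ly6G. Of the simulated calls, 1.20%, 2.78% and 2.81% were unchanged genes. The simulated reads were drawn gene by gene, without variation shared by the genes of a pool. These shares and recoveries therefore need not hold for the real pools. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.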

Results

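Liver transcriptomes were measured in 12 pools of MCD-fed male mice, 4 pools each of Lyzs-Cre controls, of Lyzs-Cre mice lacking p38γ and p38δ in the myeloid lineage (KO) and of Lyzs-Cre mice given an antibody against Ly6G (anti-Ly6G). The labels describe a comparison of the kinase deletion and of the neutrophil-directed antibody with the same Cre controls. Levels are in RPM (reads scaled to a TMM-adjusted library size), given as mean ± SD with n = 4 pools. Recovered depth was 13.1 to 22.3 M reads per pool. Pools of the same group differed by more than sampling noise (chi-square per gene 9.61 to 63.1), and their log2 values had Pearson correlations of 0.977 to 0.991 across genes. The first principal component held 46.8% of the variance and set the anti-Ly6G pools (31.2 to 36.2) apart from control and KO pools (-20.7 to -12.1). The second held 11.9% and separated control (3.68 to 20.1) from KO (-18.0 to -8.62).

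**Figure D1:**
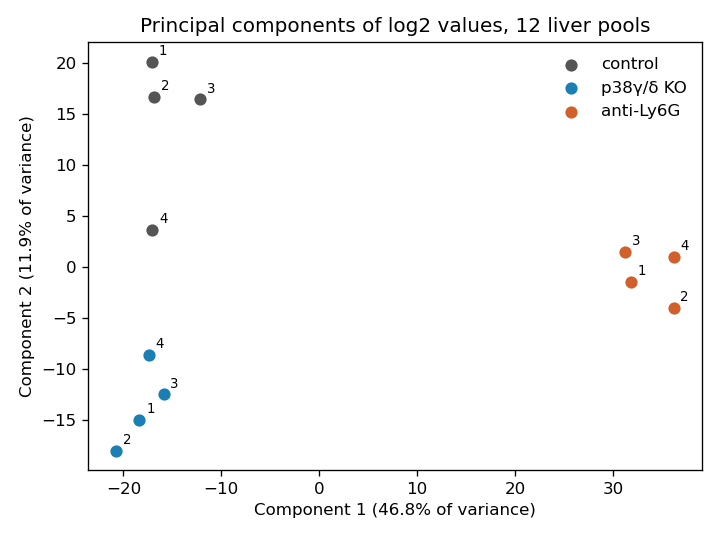
Each point is 1 liver pool, placed by its scores on the first component (x axis, 46.8% of the variance) and the second (y axis, 11.9%) of log2 values, coloured by group. The anti-Ly6G pools lie at 31.2 to 36.2 on the first component, and the control and KO pools lie below -12.

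The targeted genes were examined first. Mapk12, which encodes p38γ (ENSMUSG00000022610, chromosome 15, 89130584 to 89140703, minus strand), was near the lower end of the table, at 2.17 ± 0.397 in control, 2.30 ± 0.694 in KO and 1.67 ± 0.147 in anti-Ly6G. Its log2 fold change was 0.05 ± 0.18 (SE) in KO against control (limma, adjusted p = 0.922) and -0.29 in anti-Ly6G against control (adjusted p = 0.247). The KO value turned to -0.03 without control 2 or without KO 3 and to -0.08 without KO 4, and to -0.26 with the mitochondria label as a covariate. Whole liver holds few myeloid cells, and other cells keep the floxed genes, so this level does not test the deletion. Lyz2, the locus that drives Cre (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand), stood at 95.2 ± 49.2 in control, 196 ± 51.2 in KO and 54.0 ± 14.7 in anti-Ly6G. It was higher in KO than in anti-Ly6G by 1.85 (limma, adjusted p = 0.00525, or 1.53 and not past the threshold with KO 3 and 4 alone). Against control it did not pass the test, with 1.25 in KO (adjusted p = 0.135) and -0.61 in anti-Ly6G (adjusted p = 0.278, past the threshold at -1.15 without control 2, and turned to 0.0429 with the covariate). Only 59.5% of its 25-mers are unique, since Lyz1 is a close paralog.

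In KO against control, genes of the circadian clock fell. Ciart, a repressor of the clock's activator complex, dropped from 22.6 ± 8.79 to 3.50 ± 1.87 (log2 -2.57 ± 0.36 SE), and Per3, a period gene, dropped from 20.2 ± 6.11 to 5.97 ± 2.39 (-1.71 ± 0.29). Tef, a transcription factor under clock control chosen after its values were seen, fell from 123 ± 10.8 to 69.4 ± 15.0, and Nr1d2, a nuclear receptor of the clock's second loop, fell from 74.1 ± 4.56 to 52.4 ± 3.78. Of 15 measured clock genes, 4 fell, 0 rose and 11 did not pass, and 9 were lower when adjusted over the list alone. In anti-Ly6G against control 5 of the 15 fell (Nr1d1, Bhlhe41, Ciart, Arntl and Per1, of which Bhlhe41, Arntl and Per1 were chosen after their values were seen) and Nr1d2 rose, at limma adjusted p = 0.000690 to 0.0419. In all 4 genes that fell in KO, every KO pool lay below every control pool, with limma adjusted p from 0.0115 (Ciart) to 0.0292 (Tef). Camera gave the list an adjusted p of 4.58e-07, and adjusted p = 0.414 with an estimated correlation. Fry, which tests each list alone, gave it adjusted p = 0.0254 in a single direction. The calls depended on single libraries. Without control 2 none of the 4 passed (Ciart -2.55, adjusted p = 0.0536), without KO 3 Per3 (-1.61) and Tef (-0.77) did not, and Tef also did not pass without control 1 (-0.86) or without KO 4 (-0.74). The rule named 25 genes called in this comparison, and 170 of their 535 values in other fits, left-out libraries included, lost the call.

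**Figure D2:**
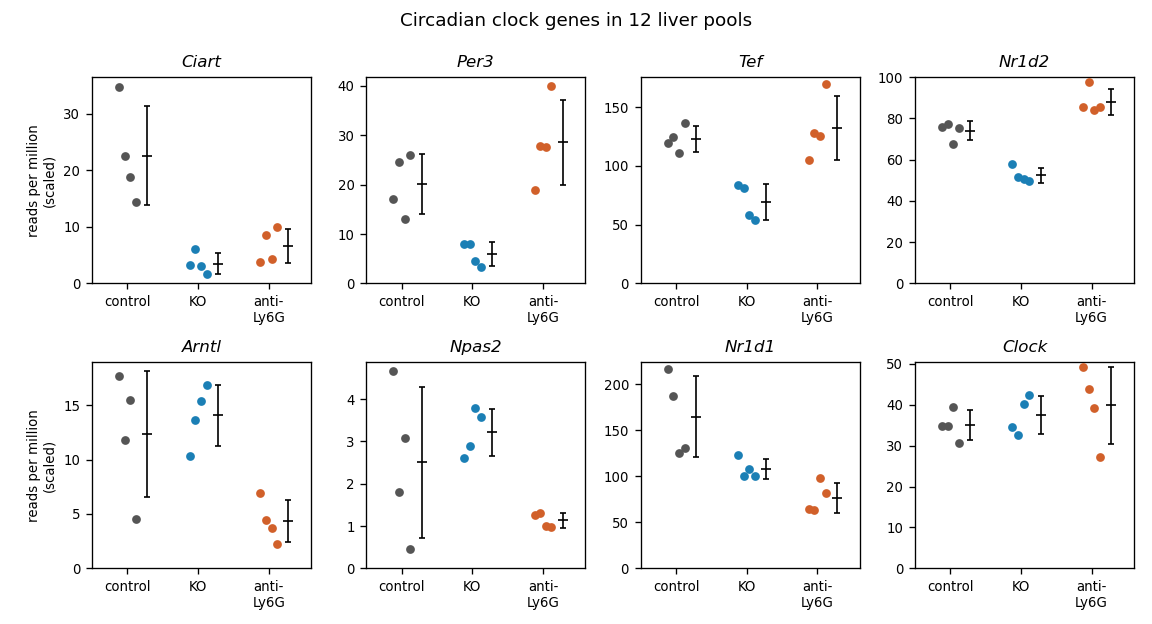
Levels of 8 clock genes (y axis, RPM, linear from 0) in control, KO and anti-Ly6G livers; points are pools, and the bar beside them is the mean ± SD of 4 pools. Ciart, Per3, Tef and Nr1d2 were lower in every KO pool than in every control pool, and Arntl, chosen with Npas2 and Clock after their values were seen, averaged 12.4 in control, 14.0 in KO and 4.35 in anti-Ly6G pools.

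Named genes changed in both directions in KO against control. The largest rises were Osbpl3, an oxysterol-binding protein relative (13.7 ± 3.95 to 30.3 ± 7.12, log2 1.13), Fam83a (1.05), Dhrs9, a retinol dehydrogenase (0.99), Smim1 (0.97), Sdr9c7 (0.95), Spon2, a secreted matrix protein (19.5 ± 2.18 to 37.4 ± 6.19, 0.91), the noncoding RNA Snhg18 (0.88) and Lst1 (0.88). The largest falls after Ciart were Usp2, a deubiquitinase (17.7 ± 6.07 to 4.64 ± 2.13, -1.86), Per3, Slc20a1, a phosphate transporter (-0.90), Phf11c (-0.90), Ppargc1b, a coactivator of mitochondrial genes (-0.88), Podxl (-0.87) and Cyp2j9 (-0.86). The naming rule required an adjusted p under 0.05 and no overlap between the 4 and 4 pools. Within that choice, limma adjusted p of the 16 ran from 0.00801 (Spon2) to 0.0415 (Osbpl3 and Ppargc1b). Of these 16, only Spon2 (ENSMUSG00000037379, chromosome 5, 33198184 to 33218455, minus strand) kept an adjusted p under 0.05 in each other fit run, with 0.83 to 1.01 when 1 library was left out, and lay below a log2 change of 1. Of the 16, 5 stayed past it without control 1, 1 without control 2, 5 without control 3, 16 without control 4, 6 without KO 1, 6 without KO 2, 5 without KO 3 and 9 without KO 4. Without control 2 their rises were 0.85 to 1.16 and their falls -2.55 to -0.83.

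The lists held few called genes in this comparison. In the stellate cell and fibrosis list, Tagln, a smooth muscle protein, rose (0.60, limma adjusted p = 0.0276) and 22 of 23 members did not pass, with 8 higher when adjusted over the list alone. Pdgfrb (0.51, adjusted p = 0.0567) and Col1a1 (0.88, 0.0903) did not pass. Tagln is uncertain, with 36.5% unique 25-mers. Nsdhl, an enzyme of cholesterol synthesis, rose (0.74, adjusted p = 0.0323) while 23 of 24 members of its list did not pass, Sqle at 0.88 (0.0679) and Hmgcs1 at 0.63 (0.0910) among them, and 5 were higher adjusted over the list alone. Among inflammatory genes Il1rn, an interleukin-1 antagonist, rose (0.73, adjusted p = 0.0459) and 16 of 17 did not pass. Zfp36, an immediate early gene whose protein destabilises cytokine mRNA, fell (-0.62, adjusted p = 0.0139), with 11 of 12 not passing and 3 lower adjusted over the list alone. Cyp3a25, a drug-metabolising P450 (-0.59, adjusted p = 0.0459), and Slc10a1, the bile salt importer (-0.49, 0.0323), fell, and Cyp3a25 is uncertain at 46.0% unique 25-mers. None of the 17 monocyte and macrophage genes passed, 5 being higher adjusted over the list alone, and Ccr2 (1.00, adjusted p = 0.0903), Chil3 (adjusted p = 0.105) and Cx3cr1 (0.90, 0.122) had the lowest p. None of the 13 endothelial genes passed, with 5 lower adjusted over the list alone and Kdr at -0.74 (0.0595). Of the 21 genes of the neutrophil list only 5 were measured, and none passed. S100a8 was at 0.13 (limma adjusted p = 0.737), S100a9 at 0.17 (0.716, -0.06 without control 1) and Cxcr2 at -0.02 (0.970, turned to 0.01 without control 4, 0.07 without KO 1 and 0.01 without KO 2). Without control 2 none of Tagln (0.58), Nsdhl (0.71), Il1rn (0.77), Zfp36 (-0.61), Cyp3a25 (-0.57) and Slc10a1 (-0.48) passed. Of these 6 and Ciart, Nr1d2 and Per3, 5 passed without control 1, 4 without control 3, 9 without control 4, 6 without KO 1, 5 without KO 2, 3 without KO 3 and 6 without KO 4.

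Over all genes, limma called 69 higher and 63 lower in KO against control (132 of 11791), and 2227 had an unadjusted p under 0.05. Of the 132, 4 rose at least 2-fold (Osbpl3, Fam83a, Gm11843 and 2010003K11Rik) and 5 fell (Ciart, Usp2, Per3, Gm26825 and ENSMUSG00000094114), of which Gm11843, 2010003K11Rik, Gm26825 and ENSMUSG00000094114 were chosen after their values were seen. In all 132 the pools did not overlap, as in 12.4% of all genes against 2.86% by chance. Every one of the 8 libraries moved this count by over 1.5 times. It was 38 without control 1, 3 without control 2, 47 without control 3, 319 without control 4, 38 without KO 1, 34 without KO 2, 23 without KO 3 and 87 without KO 4. The 3 genes called without control 2 were Spon2 (0.91), Narf (-0.71) and the pseudogene Gm11843 (1.51), and Narf and Gm11843 were chosen after their values were seen. The count was 20 with the replicate number as a block, 577 with DESeq2 and 792 with voom sample weights. With the mitochondria label as a covariate 25 rose and 54 fell, so that 31.6% of calls were higher in place of 52.3%, and with KO 1 and 2 alone, which carry the controls' label, 13 and 45 (22.4% higher). Both fits take the fold change from KO 1 and 2 against control and differ in the estimated spread alone. They are therefore not separate checks. Of the 132 reported calls, 20 were kept with the block, 34 with the covariate and 21 with KO 1 and 2 alone. Camera passed 13 of 32 lists, among them stellate and fibrosis (median 0.34, adjusted p = 4.24e-07), monocyte and macrophage (0.38, 1.87e-05) and cholesterol synthesis (0.28, 0.000330) upward and endothelial (-0.32, 6.10e-05) and hepatocyte (-0.14, 0.00840) downward. With an estimated correlation 0 lists passed, at adjusted p = 0.541 for each of these 5, and 8 passed without control 3 or without KO 3. Other splits of the same 8 libraries passed up to 18 lists.

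In anti-Ly6G against control, neutrophil, macrophage, matrix and immediate early genes fell and genes of cholesterol synthesis rose. S100a8 and S100a9, the paired calcium-binding proteins abundant in neutrophils, fell from 2.81 ± 0.626 to 0.792 ± 0.156 (log2 -1.35 ± 0.18 SE) and from 6.76 ± 2.45 to 1.85 ± 0.484 (-1.58 ± 0.22). The macrophage gene Gpnmb fell from 164 ± 79.9 to 23.0 ± 14.2 (-2.87) and the collagen gene Col1a1 from 19.6 ± 8.46 to 5.88 ± 1.12 (-1.59). Sqle, squalene epoxidase, rose from 4.16 ± 0.756 to 21.5 ± 7.57 (2.19). These 5 genes had limma adjusted p from 2.61e-05 (Sqle) to 0.000531 (Col1a1). With the mitochondria label as a covariate Gpnmb and Col1a1 no longer passed, while S100a8, S100a9 and Sqle still did. The covariate widens standard errors even if the label has no effect, so a lost call does not tie a change to the label.

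Of the 21 genes of the neutrophil list only 5 were measured, of which 4 fell and 1 did not pass. Besides S100a8 and S100a9, the lectin gene Clec4d fell (-1.59) and Csf3r, the receptor for granulocyte colony-stimulating factor, fell (-0.58), while Cxcr2, a chemokine receptor of neutrophils, was at 1.85 ± 0.0947 in control and 1.81 ± 0.414 in anti-Ly6G (-0.04, limma adjusted p = 0.872). The Csf3r call was lost without control 2 (-0.53), control 4 (-0.47), anti-Ly6G 2 (-0.50) or anti-Ly6G 4 (-0.49). Cxcr2 turned to 0.10 without anti-Ly6G 4. Of 17 monocyte and macrophage genes, 10 fell, 0 rose and 7 did not pass, with Trem2, a lipid-sensing receptor, at -1.42 and Cd68, a lysosomal macrophage protein, at -1.27. Of 23 stellate and fibrosis genes, 18 fell, 0 rose and 5 did not pass, with Col1a2 at -1.32 and Tgfb1, a fibrogenic cytokine, at -0.90. Adjusted over the list alone, 4 neutrophil, 11 macrophage and 19 stellate genes were lower. Over all 11791 genes tested, 1775 rose and 1805 fell, and small list counts have to be read beside that share. Marco, a scavenger receptor of Kupffer cells, fell (-2.06), 2 of the 9 genes of its list falling. Stab1 fell (-0.49), 3 of 13 endothelial genes falling. Neither list passed camera, and adjusted over the list alone 1 Kupffer cell gene and 2 endothelial genes were lower. Other cell type markers that fell were Ccl5 (-1.09), the B-cell gene Cd79a (-1.12), the antigen-presentation gene Cd74 (-0.62) and the bile duct gene Sox9 (-0.65). These are 1 of 2 T and NK cell genes, 2 of 6 B-cell, 4 of 9 MHC class II and 2 of 7 bile duct genes that fell, 0 rising, and none of these lists passed camera, the T and NK cell list being too short for it.

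Of 12 immediate early genes, 9 fell, 0 rose and 3 did not pass, with Zfp36 from 106 ± 14.6 to 36.3 ± 2.64 (-1.52), the phosphatase gene Dusp1 at -1.29 and Ier2 at -0.70. Of 17 inflammatory genes, 10 fell, 0 rose and 7 did not pass, with the chemokine gene Cxcl2 at -1.54, Tnfaip3, an NF-κB inhibitor, at -0.95 and Icam1 at -0.59. Adjusted over the list alone, 10 immediate early genes were lower, and 11 inflammatory genes were lower and 1 higher. Of 24 cholesterol synthesis genes, 17 rose, 0 fell and 7 did not pass, with Cyp51 at 1.93 and Nsdhl at 1.38. Adjusted over the list alone, 17 were higher and 1 lower. Of 23 nuclear genes of oxidative phosphorylation, 2 rose (Ndufb8 0.28, Uqcrc2 0.20) and 0 passed when adjusted over the list alone. Ndufb8 did not pass without control 2 (0.27), 3 (0.28) or 4 (0.25) or anti-Ly6G 1 (0.26), 2 (0.24) or 4 (0.26), nor Uqcrc2 without control 1 (0.22), 2 (0.20), 3 (0.23) or 4 (0.16) or anti-Ly6G 1 (0.16) or 2 (0.19). All named genes of this and the preceding paragraph with a change had limma adjusted p under 0.05, from 2.13e-07 (Zfp36) to 0.0486 (Uqcrc2). These 7 lists (neutrophil, macrophage, stellate, immediate early, inflammatory, cholesterol and oxidative phosphorylation) passed camera at adjusted p = 0.00806, 1.10e-05, 1.08e-07, 1.66e-05, 0.000599, 4.95e-08 and 0.0435. With an estimated correlation none did, at adjusted p = 0.560, 0.656, 0.560, 0.560, 0.560, 0.560 and 0.986, and other splits of the same libraries passed up to 18 lists. Fry in a single direction, which tests each list alone, gave the 7 lists adjusted p = 0.0024, 0.0084, 0.0024, 0.00069, 0.0024, 0.0024 and 0.245.

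Several metabolic genes changed in lists that did not pass camera. Scd1, the stearoyl-CoA desaturase, fell from 611 ± 358 to 58.4 ± 33.9 (log2 -3.34, limma adjusted p = 0.000129), and its control pools were at 302 and 301 (1 and 3) and 915 and 926 (2 and 4). Vldlr, a lipoprotein receptor, rose from 2.38 ± 0.614 to 12.6 ± 2.75 (2.20, adjusted p = 3.69e-06), and Apoa4, an apolipoprotein with 34.3% unique 25-mers, rose from 4331 ± 778 to 14751 ± 1878 (1.78, 0.000105). Cyp2b10, a P450 induced by xenobiotics, rose from 0.898 ± 0.339 to 13.7 ± 5.54 (3.27, 1.16e-05). Cth, an enzyme of cysteine synthesis from methionine (-1.17), the urea cycle gene Cps1 (-0.79), Fbp1 of gluconeogenesis (-0.58), the bile acid transporter gene Abcc3 (-0.83), Socs3 (-0.97), Rrm2 (-1.08), Ppp1r15a (-0.59) and Nr1d1 (-1.08) fell. Ugdh (1.11), Vnn1 (0.54) and Iigp1 (0.52) rose. Cux2, a female-biased factor, fell (-1.74), and Selenbp2, with 35% unique 25-mers, rose (2.10). Several of these lists moved in both directions, with 4 of 21 lipogenesis genes rising and 3 falling, 3 of 17 xenobiotic P450 genes rising and 4 falling, 2 of 15 lipoprotein genes rising and 3 falling, and 1 of 15 glucose and insulin genes rising and 5 falling. Over all 11791 genes tested, 1775 rose and 1805 fell. Limma adjusted p of the genes named without one ran from 0.000104 (Ugdh) to 0.0138 (Iigp1).

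**Figure D3:**
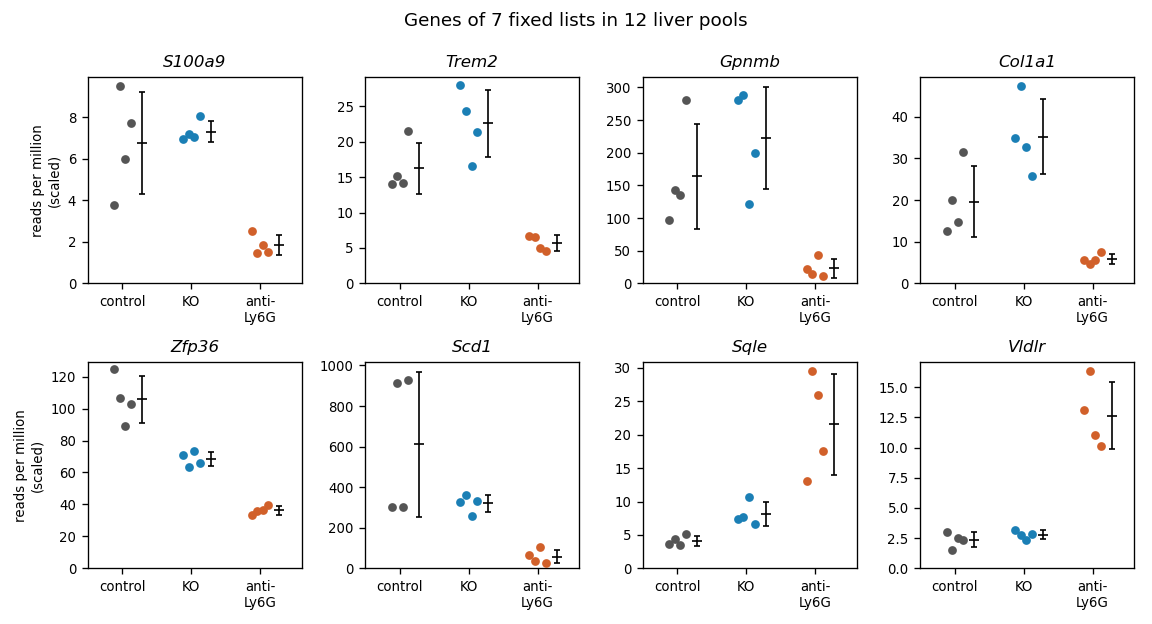
Levels of 8 genes from 7 gene lists (y axis, RPM, linear from 0) in control, KO and anti-Ly6G livers; points are pools, and the bar beside them is the mean ± SD of 4 pools. S100a9, Trem2, Gpnmb, Col1a1, Zfp36 and Scd1 averaged 1.85, 5.72, 23.0, 5.88, 36.3 and 58.4 in anti-Ly6G pools, below control, and Sqle and Vldlr averaged 21.5 and 12.6, above it.

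The largest changes in anti-Ly6G against control lay mostly in genes with near-identical copies, and their levels are uncertain. Atp6v0c-ps2 (2.95% unique 25-mers) averaged 0.570 ± 0.232 in control and 116 ± 18.7 in anti-Ly6G pools, Rps13-ps1 (5.25%) 0.110 ± 0.221 and 58.5 ± 2.72, Rps2-ps10 (2.03%) 0.0495 ± 0.0991 and 42.0 ± 4.75, and Hmga1b (5.74%) 0.0661 ± 0.132 and 20.3 ± 3.06. Other genes with shared sequence were lower, Rps13-ps2 and Hmga1 being relatives of genes that rose. Rps13-ps2 (0% unique) averaged 87.6 ± 5.18 in control and 7.90 ± 7.88 in anti-Ly6G pools, Hmga1 (35.4%) 51.3 ± 3.71 and 10.4 ± 1.42, Rpl29 (52.4%) 75.1 ± 18.3 and 9.43 ± 8.05, and Pgk1-rs7 (0%) 31.5 ± 12.4 and 0.179 ± 0.358. Cyp2c39 (65.5%) averaged 6.74 ± 1.64 and 440 ± 45.0, and Mup2 (20.8%) 93.4 ± 60.2 and 2439 ± 814. Among genes of more distinct sequence, Myom2, a sarcomere gene (98.4% unique), was at 0.215 ± 0.155 and 13.4 ± 6.00, Gdpd3 (88.6%) at 0.184 ± 0.130 and 12.9 ± 4.49, Acpp (98.0%) at 9.99 ± 2.49 and 0.656 ± 0.702, and Trim12a (81.8%) at 5.79 ± 2.01 and 0.486 ± 0.227. All of these passed limma, as the naming rule required, from adjusted p = 1.60e-11 (Rps2-ps10) to 0.00428 (Mup2).

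Over all genes, limma called 1775 higher and 1805 lower in anti-Ly6G against control (3580 of 11791), with 157 and 198 changed at least 2-fold, and no single library moved either count by over 1.5 times. In 2774 of the 3580 the pools did not overlap, as in 27.3% of all genes against 2.86% by chance. The mitochondria label differs between all pools of these groups, and with it as a covariate, estimated within the KO group, 517 rose and 456 fell. The label was estimated from 2 KO pools of each kind. Standard errors are therefore wider, and calls drop even if the label has no effect. Under that covariate Gpnmb (-2.01), Cd68 (-0.85), Col1a1 (-1.11), Col1a2 (-1.06), Tgfb1 (-0.83), Clec4d (-0.83), Csf3r (-0.91) and Icam1 (-0.48) no longer passed, nor did Ccl5, Cd74, Ciart, Cth, Cux2, Fbp1, Nr1d1, Pgk1-rs7, Ppp1r15a, Rps13-ps2, Rrm2, Socs3 and Uqcrc2. S100a8, S100a9, Trem2, Sqle, Cyp51, Zfp36, Scd1 and Vldlr still passed. Csf3r lost its call although its fall was larger than in the reported fit (-0.58).

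KO against anti-Ly6G asks how the kinase deletion and the antibody differ. Lyz2 was higher in KO, and Mapk12 did not differ past the threshold (0.34, limma adjusted p = 0.192, or 0.64 and past it with KO 3 and 4 alone). Macrophage genes were higher in KO for 16 of 17 members, stellate and fibrosis genes for 19 of 23, inflammatory genes for 10 of 17, immediate early genes for 8 of 12, MHC class II genes for 7 of 9, B-cell genes for 4 of 6 and neutrophil genes for 4 of 5, with 0 lower in each. Cholesterol synthesis genes were lower in KO for 15 of 24, nuclear oxidative phosphorylation genes for 7 of 23 and mitochondrially encoded genes for 4 of 13, with 0 higher in each. Over all 11791 genes tested, 1608 were higher and 1549 lower. Adjusted over the list alone the list counts were 16, 20, 11, 9, 7, 5 and 4 higher, and 15, 12 and 4 lower. These 10 lists passed camera, from adjusted p = 1.66e-14 (stellate) to 0.0240 (B cell). With an estimated correlation none did, the lowest being adjusted p = 0.261 (stellate and inflammatory), and other splits of the same libraries passed up to 18 lists. Fry in a single direction, which tests each list alone, gave the 10 lists adjusted p from 0.000367 (stellate) to 0.0476 (mitochondrially encoded).

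The 5 largest rises in KO against anti-Ly6G were Rpl34-ps1 (72.3 ± 22.3 against 0.165 ± 0.329), Rps13-ps2 (69.5 ± 4.62 against 7.90 ± 7.88), Mup13 (17.3 ± 9.80 against 0.996 ± 0.848), Gpnmb (222 ± 78.5 against 23.0 ± 14.2, log2 3.35) and Rpl29 (70.9 ± 22.6 against 9.43 ± 8.05). The 5 largest falls were Atp6v0c-ps2, Rps13-ps1, Rps2-ps10, Cyp2c39 and Eno1b (29.9 ± 58.8 against 240 ± 90.4). All but Gpnmb are uncertain, with at most 9.13% unique 25-mers (Eno1b) apart from Rpl29 (52.4%) and Cyp2c39 (65.5%). Limma adjusted p ran from 1.24e-11 (Rps2-ps10) to 0.0436 (Mup13). The Mup13 call held without KO 2 alone and was lost without each of KO 1 (3.61), KO 3 (3.40), KO 4 (3.29), anti-Ly6G 1 (3.81), anti-Ly6G 2 (3.52), anti-Ly6G 3 (3.14) and anti-Ly6G 4 (3.88). Limma called 1608 genes higher and 1549 lower (3157 of 11791), with 266 and 128 changed at least 2-fold. In 2635 of these the pools did not overlap, as in 27.3% of all genes against 2.86% by chance. With KO 3 and 4 alone, which carry the label of the anti-Ly6G pools, 1070 were higher and 971 lower, and Eno1b (-3.85) no longer passed.

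Both comparisons with control share its 4 pools. Of the genes called in both, 45 rose and 39 fell in both. Independent calls would give 10.4 and 9.64, a figure that ignores the shared pools. Simulated experiments of unchanged groups, in which no gene truly changed, gave a mean of 0. That mean is no baseline for groups in which genes do change, and no such baseline was run. The largest shared changes were Ciart (-2.57 in KO and -1.73 in anti-Ly6G), Cyp2j9 (-0.86 and -0.86), Zc3h6 (-0.85 and -1.41), the transcription factor gene Sox12 (-0.85 and -1.62) and Sdr9c7 (0.95 and 0.84). Opposite directions were called for 5 genes, chosen after their values were seen apart from Tagln and Nr1d2. Adamts2 (0.45 and -0.50), the collagen gene Col6a3 (0.65 and -0.81), Ccnf (0.61 and -0.78) and Tagln (0.60 and -0.35) were higher in KO and lower in anti-Ly6G, and Nr1d2 (-0.50 and 0.25) the reverse, with limma adjusted p from 0.000640 to 0.0492. Across genes, the fold changes had r = 0.219 (jackknife SE 0.0762) against 0.513 in 20 simulated experiments of unchanged groups. The shared pools alone set the simulated r, and changes in a single group lower r, so the lower value does not measure how much the effects share. The covariance was 0.0278 against 0.0149, a difference of 0.0129. With the controls split into pairs, r was 0.0228 to 0.186, the mean covariance was 0.0130, and 89, 1, 38, 4, 1 and 3 genes were shared in the same direction in the 6 assignments, with 10, 3, 20, 5, 0 and 0 in opposite directions. Genes are not independent replicates.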

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

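Of the tests in this part, those of shared reads, genetic background, the mitochondria label, time of day, a single library and cell numbers were chosen only after the results they bear on were seen, and those of the label, the single library and cell numbers replaced earlier forms whose results were known. Among 363 groups of 4 pools examined for the genes named, 19 held 1 pool set far apart from the other 3 relative to the group's range, and chance gives about 1 in 20, or 18.2. In genes of more distinct sequence these were Clec4d at 0.808 in anti-Ly6G 4 (others 1.93 to 2.09), Cyp8b1 at 615 in anti-Ly6G 3 (404 to 429), Nr1d2 at 97.6 in anti-Ly6G 2 (84.1 to 85.6), Acpp at 1.71 in anti-Ly6G 1 (0.238 to 0.355), Trem2 at 21.5 in control 4 (14.1 to 15.2), Fbp1 at 917 in anti-Ly6G 3 (621 to 651), Ugdh at 83.7 in control 4 (53.2 to 57.1) and Ndufb8 at 101 in anti-Ly6G 3 (122 to 126). In genes with close copies they were Cyp2c39 at 507 in anti-Ly6G 3 (412 to 422), Rpl29 at 21.4 in anti-Ly6G 1 (4.15 to 6.14), Rps2-ps10 at 49.1 in anti-Ly6G 4 (39.2 to 39.8) and Eno1b at 118 in KO 3 (0 to 1.63). A pool stood alone above 0, with its group's other pools at 0, for Atp6v0c-ps2 (0.686 in KO 2), Rps13-ps1 (0.441 in control 1), Rps2-ps10 (0.198 in control 4), Hmga1b (0.264 in control 4 and 0.0528 in KO 2), Pgk1-rs7 (0.715 in anti-Ly6G 3) and Rpl34-ps1 (0.659 in anti-Ly6G 2).

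The first pattern was a set of 22 genes that separated the 4 anti-Ly6G pools from the 8 others, with all pools of one side at 2 or above and all of the other under 1 (18 on and 4 off in anti-Ly6G), with 0 such genes for control or KO pools alone. The mitochondria label is argued against as a common cause, because KO 3 and 4, which share the label NZB, lay a median of 0% of the way from KO 1 and 2 to the anti-Ly6G pools in 23 genes chosen by the same levels without use of KO 3 and 4 (-16.6% to 76.7%, 1 gene, Gm10171, named after its values were seen, being at least halfway). Reads shared between near-identical copies could account for part of the set but cannot be told apart from a real change there, since 18.2% of the 22 genes had at least 90% unique 25-mers (73.1% of all genes), a share between the bounds set for either reading. They are no cause for genes of unique sequence such as Myom2, S100a8 and Acod1. A different nuclear background of the anti-Ly6G mice may contribute, as 4 of the 22 genes lay within 1 Mb of another (permutation p = 0.0499, 10000 draws), namely H2-Bl and Gm20478 in the MHC region of chromosome 17 (70.4% and 65.1% unique 25-mers) and Mettl7a2 and Mettl7a3, but only narrowly, because the latter are also sequence relatives and the 4 unique genes held 0 such neighbours. The antibody itself and any other difference common to the anti-Ly6G pools stay open and untested. The design cannot tell them apart, and this limit holds for every gene called in anti-Ly6G against control.

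The second pattern was the fall of clock genes in KO pools (4 of 15, with 5 lower and 1 higher in anti-Ly6G pools). A single library is argued against as the whole cause, since the median log2 fold change of all 15 measured clock genes, -0.58, kept at least 83.5% (-0.48 without control 1) when any 1 of the 8 libraries was left out. The calls themselves did depend on control 2, without which 0 of the 4 remained and the whole comparison dropped from 132 calls to 3; a count of lost calls and the fold kept by the called genes were the earlier forms of this test. Another time of day at collection stays open, since the 12 other clock genes lay below the activators Arntl, Clock and Npas2 by a median difference of -1.09, as a shifted phase allows, though this difference partly restates the fall that prompted the test and is no evidence for that source. A change of the clock by genotype itself predicts the same and may equally be the source. No collection times were used for any group, so a difference in time of day was not tested for the anti-Ly6G pools either.

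The third pattern was the fall of macrophage, neutrophil and fibrosis genes in anti-Ly6G pools. Fewer cells of every non-hepatocyte type may be part of the cause and cannot be told apart from a loss of single types, for neutrophils or for the 7 other lists. The medians of these 7 lists (at least 5 measured genes, erythroid genes left out) had a range of 0.594, from -0.76 (macrophage) to -0.17 (endothelial), and 4 of the 35 splits of the 8 pools gave a range as large (highest other 0.835). The neutrophil list (-1.35) holds 5 genes of the cells that an antibody against Ly6G targets, though the sample titles read GR1. With this list the range was 1.18, and the real split alone gave a range as large (1 of 35). The range over all 8 lists was thus larger than in any other split. The distance of the neutrophil list from the others was not tested. The splits show what no group difference gives and do not model an equal loss of cells, so they cannot decide that question. A loss of these cell types after the antibody, lower expression within them, or a difference of background or mitochondria label between the mice may each be the source, and the design does not separate them. With the label as a covariate Gpnmb, Cd68, Col1a1, Col1a2, Tgfb1, Clec4d and Csf3r no longer passed, while S100a8, S100a9 and Trem2 still did. That fit has wider standard errors even if the label has no effect. It therefore does not sort these genes by their source.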

How the results depend on the processing

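The edgeR test and the restriction to protein-coding genes of unique sequence were chosen after seeing the data; the other alternatives were planned before the data were examined. Of values for named genes, 3712 kept direction and side of the threshold, 328 lost and 73 gained a call and 18 changed direction, none of these being past the threshold in the reported fit. Among named and called genes, 1 of 25 (KO against control), 52 of 106 (anti-Ly6G against control) and 7 of 11 (KO against anti-Ly6G) kept an adjusted p under 0.05 and their direction in every other fit run, the stricter thresholds not being counted here. For KO against control, calls higher and lower were 268 and 309 with DESeq2, 381 and 411 with voom sample weights, 25 higher with the mitochondria label as a covariate, 13 higher with the matching label alone, 2 and 1 at an adjusted p under 0.01 (Gm11843, Spon2 and Narf, of which Gm11843 and Narf were chosen after their values were seen) and 4 and 5 at a log2 change of at least 1. For anti-Ly6G against control they were 517 and 456 with the covariate, 921 and 951 at 0.01 and 157 and 198 at a log2 change of 1. For KO against anti-Ly6G they were 1070 and 971 with the matching label, 1015 lower in unique protein-coding genes (fewer genes tested), 880 and 693 at 0.01 and 266 and 128 at a log2 change of 1. For both comparisons with KO, the covariate and the matching label gave the same fold changes and differed in the estimated spread alone. With the replicate number as a block, KO against control had 10 higher and 10 lower, and no other count moved by over 1.5 times; same-numbered pools did not deviate together (4 of 12 pairs over 0.1, from -0.209 to 0.172, and 4 of 12 libraries best with their own number). With 1 library left out, calls ranged from 2 to 177 higher and 1 to 142 lower in KO against control, and lists from 8 to 14. Lists past the threshold were 0, 0 and 0 with an estimated correlation. In KO against control, fry passed 1 list in a single direction (clock) and 8 in mixed directions. In the same order it passed 8 and 27 in anti-Ly6G against control and 12 and 29 in KO against anti-Ly6G. Fry tests each list alone. Directions turned for Mapk12 in KO (-0.26 with the covariate and -0.26 with the matching label, -0.0814 to 0.16 with 1 library left out), S100a9 in KO (-0.0611 to 0.35), Cxcr2 in KO (0.00140 with upper-quartile factors, 0.00442 with DESeq2, 0.0185 with voom weights, 0.000840 with edgeR, -0.0976 to 0.0723 with 1 library left out), and in anti-Ly6G for Cxcr2 (0.0365 with voom weights, -0.11 to 0.0953), Lyz2 (0.0429 with the covariate), Hbb-bs (-0.24 with the covariate) and Hba-a2 (-0.28 to 0.19). The correlation of both effects moved from 0.219 to 0.0974, 0.0687, 0.0228, 0.118 and 0.0642 with KO set against controls 1 and 2, 3 and 4, 1 and 3, 2 and 4, and 2 and 3. Genes shared by both effects were 1 at 0.01 (Gm11843), and 1, 38, 4, 1 and 3 with KO set against controls 3 and 4, 1 and 3, 2 and 4, 1 and 4, and 2 and 3. Apart from fewer samples or genes and stricter thresholds, the cause was not tested. The fits without a filter and with a minimum in 4 libraries removed no gene and are void as tests of stability, and matching the mitochondria label was not run for anti-Ly6G against control, which share no label. Depth limits genes near 3 reads, a signal of 0.125 to 0.242.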

Other observations

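The tests of other splits in this part were planned before their results were seen, and Gm26825, Gm11843, Narf and Acod1 were chosen after their values were seen. The fold of largest size in KO against control belonged to the lincRNA Gm26825 (chromosome 5, 5781530 to 5783636, plus strand), at 227 ± 162 in control, 1.12 ± 1.43 in KO and 558 ± 108 in anti-Ly6G pools (log2 -6.73 in KO, limma adjusted p = 0.0115). The pseudogene Gm11843 rose from 2.09 ± 0.372 to 7.39 ± 1.12 in KO (1.61, adjusted p = 0.00139), and Narf fell from 44.5 ± 4.45 to 26.1 ± 1.52 (-0.76, adjusted p = 0.00707). In anti-Ly6G pools Acod1, which makes itaconate in activated macrophages, fell from 3.47 ± 1.57 to 0.494 ± 0.263 (-1.95, adjusted p = 0.000251).

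Several lists held called genes in anti-Ly6G against control and did not pass camera. Over all 11791 genes tested, 1775 rose and 1805 fell in that comparison. In the endoplasmic reticulum stress list 5 of 16 members rose and 3 fell, in the bile acid list 4 of 16 rose and 4 fell, and among male-biased liver genes 5 of 14 rose and 0 fell. Of 19 genes of lipid droplets and uptake 4 rose and 5 fell, and of 22 genes of methionine, choline and folate metabolism 3 rose and 4 fell. Of 26 genes of fatty acid oxidation 3 rose and 2 fell, of 15 clock genes 1 rose and 5 fell, of 22 interferon-response genes 2 rose and 2 fell, and of 22 cell cycle genes 2 rose and 2 fell. In KO against control, of all members of these lists other than clock genes only Slc10a1 of the bile acid list passed (-0.49, limma adjusted p = 0.0323), falling. The cell cycle list passed camera there (adjusted p = 0.0213), with 0 members past limma and 3 higher adjusted over the list alone, and did not pass with an estimated correlation.

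Within the KO group, pools 1 and 2 (C57 label) and pools 3 and 4 (NZB label) had residual correlations across genes of 0.101 and 0.163 within the pairs and -0.587 to -0.536 across them. Residuals from a mean of 4 pools correlate negatively by construction, and values as low occurred within a single label (-0.607 for control 1 with control 4), but the values of these same-label KO pairs were the only ones above 0 of the 18 pairs within groups. On the third principal component KO 1 and 2 lay at 10.8 and 13.3 and KO 3 and 4 at -11.8 and -14.2, and chi-square per gene was 12.3 and 9.61 within the pairs and 22.3 to 43.4 across them. The KO pools thus parted 2 and 2 along the label, while the anti-Ly6G pools, all with the NZB label, spread from -13.0 to 18.1 on that component, and the source of the KO division was not tested. The median difference of the 13 mitochondrially encoded genes, pools 3 and 4 minus 1 and 2, was -0.12 on the log2 scale (-0.25 to 0.04).

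Chance division of the pools is argued against, but not excluded, for the counts of genes called. The real split alone is the smallest share that 35 splits can give. Splits that mix the groups widen the spread within them and so call fewer genes. In KO against control the 132 calls also dropped to 3 without control 2. In each comparison only 1 of the 35 splits into 4 and 4 pools, the real one, gave as many calls, with 132 against a highest other of 1 in KO against control, 3580 against 0 in anti-Ly6G against control and 3157 against 6 in KO against anti-Ly6G. Chance cannot be excluded for the number of lists past camera. As many lists passed in 7 of 35 splits for KO against control (13 lists, highest other 18), 23 of 35 for anti-Ly6G against control (7 lists, highest other 18) and 15 of 35 for KO against anti-Ly6G (10 lists, highest other 18).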
